A study of Drosophila melanogaster with 2 samples.

How the data were processed

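The samples were 2 biological replicates (numbers 2 and 3, each with technical replicate 1) of whole Drosophila melanogaster embryos of pooled sex, aged 0 to 14 h, from a line with CG10979 fused to green fluorescent protein. Per the labels' protocols, chromatin was sheared by sonication to 200 to 800 bp and precipitated with an antibody against the fluorescent protein. Both samples belong to 1 group, since their labels name the same insertion and stage.

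The authors deposited peaks in narrowPeak form on build dm6. Per the labels and the text deposited with the lists, each replicate's peaks were called on its own alignment, the pooled peaks on both alignments together, all against the same control alignment, and the IDR list was derived from the replicates' and the pooled lists. The peak caller, the aligner and their versions are not given in the sources used here. The signal value of each peak is a score that the authors' caller gave, which has no fixed range and moves with depth. The −log10 q value deposited for each peak is capped, at 4.27 for all 7630 IDR peaks, and was therefore not used for ranking. The deposited summit offset gave each peak's summit. Each relaxed list holds 30000 peaks, a round length that may cut off weak peaks. The control alignment, the reads and the coverage tracks were not analysed here. The lists give no counts, so that depth is unknown and intervals on shares of peaks or genes cover only the number of peaks or genes.

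Gene positions came from Ensembl release 115 and sequence from the NCBI RefSeq genome, both of the Release 6 assembly that dm6 denotes, and all peaks of the 4 lists fell within the lengths of the 6 chromosome arms 2L, 2R, 3L, 3R, 4 and X. Transposable element entries were left out. Coordinates are counted from 1. Peaks were ranked by signal value within a list. For values per replicate, each replicate's own 7630 strongest peaks were taken, as many as the IDR list holds, and are given as mean ± SD (n = 2). The pooled peaks without an IDR call, which could have entered the IDR list, served as background for location and chromosomes.

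Replicate overlap counted summits within 100 bp, with chance from 1000 circular rotations of 1 list along each chromosome. Shares were compared with Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over the 6 arms, the 5 location classes or the 24 gene lists. A gene had a peak when an IDR summit lay within 500 bp of any of its annotated starts, and the background was all other protein-coding genes. List symbols not found under that name in the annotation were left out, 1 or 2 in each of 8 lists, as with 15 of 17 DNA replication factors found. Median log2 signal values were compared by a two-sided permutation test with 100000 resamples over peaks. All 2080 6-mers and 33 preset motifs were scored as present or absent, on either strand, in the 101 bp around each IDR summit and in windows of the same size centred 300 bp to either side. The exact sign test used the flank at lower coordinates, and printed flank shares are the mean of both flanks. Peaks and genes are not replicates of the experiment, and the tests over them describe these 2 replicates.

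The tests, gene lists, motifs and most alternatives were fixed before the data were examined. So was the rule for named items: the tagged gene, the gene with the nearest start for the 20 strongest IDR peaks, up to 4 members per list with the strongest peak at a start, in lists past an adjusted p of 0.05 also up to 2 members without a peak in alphabetical order, the 5 6-mers with the smallest p, and every preset motif past the threshold. An item that this rule names is not reported here. Alternatives were each replicate alone, the 3815 IDR peaks with the highest signal value, start windows of 200 and 1000 bp, overlap of at least 1 bp or a reciprocal 50%, the top 1000 peaks, other backgrounds, gene clusters counted once, and summit windows of 51 and 201 bp. GC content, windows matched on it, 1 start per gene, and lists without peaks that hold a CTCF-type sequence were added after seeing the data.

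The statistics were tested on simulated data. For the 6-mer test, a word planted in 5% of 7630 random windows ranked first, and the 3 other 6-mers called all shared 4 bases with it. The simulated summit and flank windows had the same base composition, unlike the real ones (31.8% and 44.7% GC). This simulation therefore does not cover calls that a difference in base composition brings about. For the gene list test on the 24 lists, the mitochondrial ribosomal protein list with a planted share was found in 92 of 100 simulations, with 4 calls of other lists in all. Genes were drawn independently there, whereas 1 real summit can count for neighbouring genes. For the replicate overlap, 50.6% was found where 50% of 7630 peaks were planted as shared. The work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.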

Results

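Chromatin immunoprecipitation followed by sequencing (ChIP-seq) mapped where the protein of the fly gene CG10979, carrying green fluorescent protein at its C terminus, was found along the genome of whole Drosophila melanogaster embryos of mixed sex, collected 0 to 14 h after egg laying. The tagged protein was pulled down with an antibody against the fluorescent tag. The series holds 1 group with 2 biological replicates, numbered 2 and 3, and no second condition, so the comparisons are between the replicates and between classes of genomic positions. The deposited values are 4 peak lists on build dm6. Each replicate and the pool of both has a relaxed list of 30000 peaks, and 1 further list of 7630 peaks is the authors' list at their threshold of the irreproducible discovery rate (IDR), a measure of how far peak ranks hold between replicates. The signal value printed for each peak is the authors' own and serves to rank peaks within a list. Read depth is unknown, since the lists hold no counts.

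The locus of the tagged gene itself was examined first. CG10979 (FBgn0037379) lies on chromosome 3R at 5794705 to 5799994 on the plus strand of dm6, and no IDR peak had its summit within 2 kb of the gene. The strongest peak of the pooled list at its start had its summit at 5794411, 294 bp upstream of the annotated start, with a signal value of 140.5 and rank 10235 of 30000. In replicate 2 the peak with its summit at the same base had a signal value of 73.2 (rank 10279), and in replicate 3 the nearest counterpart, at 5794333, had a signal value of 75.3 (rank 10129). Replicate 3 also had peaks inside the gene at 5795039 (76.8) and 5798495 (78.7). Each pooled peak at the gene had a signal value below 189.9, the lowest of the IDR list. A peak at the native gene and one at the inserted tagged copy cannot be told apart from these lists.

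The 2 replicates were compared to ask how far they marked the same positions in the embryo. Of the 7630 peaks with the highest signal value in each replicate, 80.8% had a summit within 100 bp of a summit of the other replicate. Lists rotated at random along the chromosomes gave 1.15% ± 0.127 (SD, 1000 rotations) and at most 1.64%, with a permutation p of 0.001, the smallest that 1000 rotations can give. Of the IDR peaks, 98.4% had a counterpart in the relaxed list of replicate 2 and 97.9% in that of replicate 3. The IDR list was derived from these lists and the pooled list, so that such a match follows in large part from the selection. Across the 7351 IDR peaks matched in both replicates, signal values had a Spearman correlation of 0.881 and a Pearson correlation of 0.917 on the log2 scale. These correlations are across peaks, which are not independent replicates, and they cover peaks selected for a high pooled signal value and for a match in both replicates, so that they describe those peaks only.

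The replicate 2 to replicate 3 ratio of signal values had a median log2 of 0.28 with an SD of 0.44 across these peaks. Among the strongest peaks the ratio fell into separate bands. The peaks at siz (log2 ratio −0.57), near snRNA:U5:14B (−0.66), Mtpalpha (−0.64), crp (−0.58) and Tpst (−0.61) were stronger in replicate 3, whereas the other 15 of the 20 strongest peaks had ratios between 0.27 and 0.53. At the ribosomal protein gene RpS28a the signal value was 1496 in replicate 2 and 2202 in replicate 3.

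**Figure D1:**
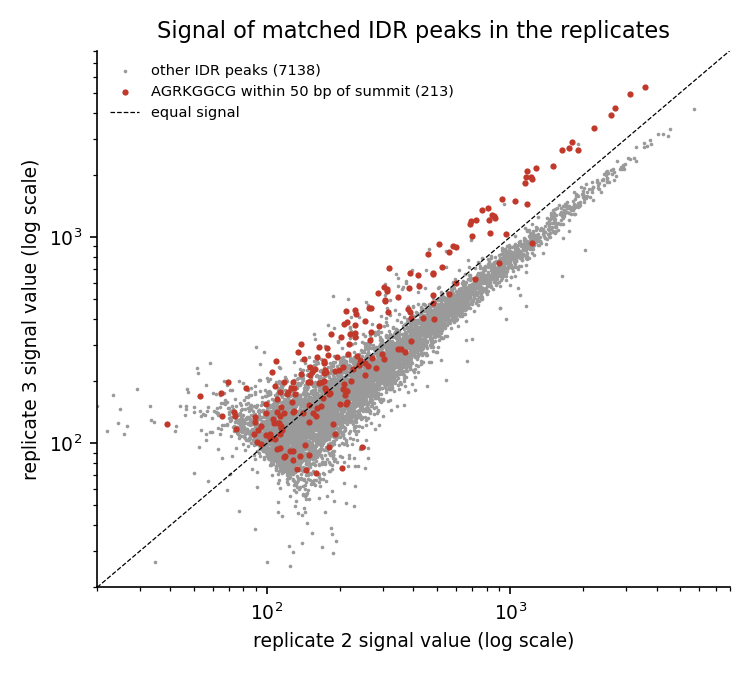
Signal value of each matched IDR peak in replicate 2 (horizontal, log scale) and replicate 3 (vertical, log scale), with the line of equal signal dashed. Of the 7351 peaks, the 213 that hold AGGTGGCG or a related sequence, picked after the ratios were seen, within 50 bp of the summit (red) had a median log2 ratio of −0.40, and the other 7138 (grey) a median of 0.29.

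The strongest IDR peaks lay at or near genes of varied function. The highest signal value, 9874, belonged to a peak 207 bp from a start of px, a gene of wing vein patterning, at 22513980 to 22514598 on chromosome 2R. It was followed by a peak in an intron of siz, which encodes an activator of Arf GTPases (8952, chromosome 3L), and by an intergenic peak 9212 bp from snRNA:U5:14B, a gene for a spliceosomal RNA (8069, chromosome X). The fourth, with a signal value of 7905, lay in an intron of ush, which encodes a cofactor of GATA factors, and 1392 bp from the start of cbt, a zinc finger transcription factor gene. Of the 20 strongest peaks, those at px, Ugalt, CG14100, Mtpalpha, Art3, crp, ph-p, CG18549, Chro, CG11309, Fkbp14, Tpst and CG5611 had their summits within 500 bp of a start. The peak at Art3, an arginine methyltransferase gene, also lay 135 bp from a start of mRpS10, a mitochondrial ribosomal protein gene. The remaining peaks lay in introns of CG11050 and Lk6, a protein kinase gene, and between genes 3757 bp from CG31668 and 4667 bp from CG13321. The IDR list made up 25.4% of the pooled list and consisted of its 7630 peaks with the highest signal value, the lowest at 189.9.

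Along the chromosomes, IDR peaks were less frequent on 2R and on the small chromosome 4, and more frequent on 3L, than the 22370 pooled peaks without an IDR call. Chromosome 2R held 16.9% of the IDR peaks and 19.9% of the others (0.85-fold, Fisher's exact test, adjusted p = 4.8e-08), with 17.1% ± 0.482 (SD, n = 2) in the replicates' own top lists. Chromosome 4 held 25 IDR peaks, 0.328% against 0.541% (0.606-fold, adjusted p = 0.029 by the exact test). The shares were 22.4% against 20.5% on 3L (exact test, adjusted p = 0.0010), 23.5% against 21.8% on 3R (adjusted p = 0.0064) and 18.8% against 19.9% on X (adjusted p = 0.029), whereas 2L did not pass (18.2% against 17.3%, adjusted p = 0.11). Peak density ran from 18.8 per Mb on chromosome 4 to 61.1 per Mb on 3L. Only 2R and 3L kept their calls in each replicate alone and among the 3815 strongest IDR peaks. In that stricter set 2L was called as well. Against the length of each chromosome, 3R (0.978-fold) and X (1.07-fold) changed direction.

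Peak summits gathered at gene starts and were scarce in exons. Of the IDR peaks, 3071 (40.2%, 95% Wilson interval 39.2 to 41.4%) lay within 500 bp of an annotated transcription start, against 33.5% of the other pooled peaks (1.20-fold, Fisher's exact test, adjusted p = 1.2e-25) and 13.6% ± 0.613 (SD) of IDR summits rotated along their chromosomes. The replicates' own top lists gave 40.8% ± 2.64 (SD, n = 2). Exons away from starts held 2.88% of the IDR peaks and 11.1% of the others (0.260-fold, exact test, adjusted p = 2e-126). Introns held 37.6% against 39.8%, intergenic sequence within 5 kb of a gene 14.1% against 11.7%, and intergenic sequence farther away 5.18% against 3.93%. Each of these 3 differences passed the exact test as well (adjusted p = 7.6e-04, 5.7e-08 and 7e-06). Of the peaks at starts, 77.2% had their summit upstream of the nearest start, at a median of −107 bp, and 37.3% lay within 100 bp of it.

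**Figure D2:**
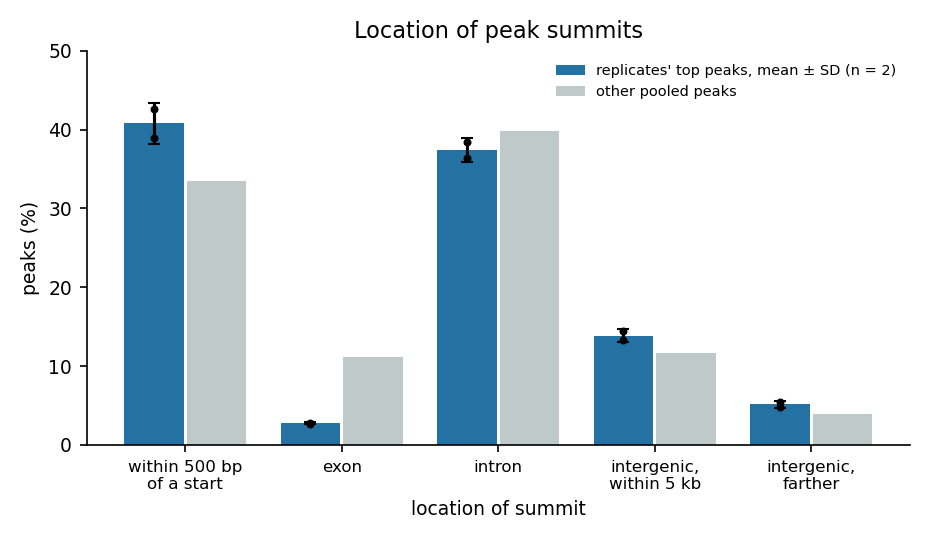
Share of peak summits (vertical, %) in each class of genomic location. Blue bars are the mean ± SD of the replicates' top 7630 peaks (n = 2, dots are the replicates) and grey bars the 22370 pooled peaks without an IDR call. Exons held 2.75% of the replicates' peaks and 11.1% of the others.

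Peaks at starts were slightly weaker than peaks elsewhere in the IDR list, with median signal values of 362.2 and 382.9 (log2 difference −0.08, permutation p = 0.0131). The difference was −0.16 in replicate 3 (permutation p = 1e-05, the smallest that 100000 resamples can give) and −0.01 in replicate 2 (permutation p = 0.763). With a start window of 200 bp it was −0.26 (permutation p = 1e-05) and with 1000 bp −0.05 (permutation p = 0.11), and among the 3815 strongest IDR peaks the direction turned, to 0.20 (permutation p = 1e-05).

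Genes of the cytoplasmic ribosome carried peaks at their starts far more often than other genes, and genes of the mitochondrial ribosome did so more often. An IDR summit lay within 500 bp of a start of 3520 of the 13945 protein-coding genes (25.2%), 3399 in replicate 2 and 3661 in replicate 3. Among the genes for proteins of the cytoplasmic ribosome it was 74 of 93 (79.6%, 95% Wilson interval 70.3 to 86.5%, 3.20-fold, Fisher's exact test, adjusted p = 1.1e-26), and 80.1% ± 0.760 (SD, n = 2) in the replicates' own lists. RpS28a (signal value 3719), RpL34b (1206) and RpL32 (1141) were among those with the strongest peaks, and RpL10 and RpL10Aa had none. The list was drawn by gene symbol, so that it takes in copies and genes named as like a ribosomal protein. Of these RpL24-like and RpS14b had a peak, for example, and RpL7-like and RpS15Ab had none. Genes for proteins of the mitochondrial ribosome had a peak in 39 of 73 cases (53.4%, 2.13-fold, exact test, adjusted p = 1.5e-06), led by mRpS10 (6696), mRpL41 (4961), mRpS23 (4553) and mRpL23 (3041), while mRpL10 and mRpL12 had none. Among the 3815 strongest IDR peaks the mitochondrial list did not pass (17 of 73 genes, exact test, adjusted p = 0.056).

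Cell cycle regulators and genes for insulator and architectural proteins also had peaks more often. Of 18 cell cycle regulators 11 had a peak (61.1%, 2.43-fold, exact test, adjusted p = 0.0054), with CycE, a cyclin gene of S phase entry (1804), Dp (866.2), Cdk1 (594.9) and E2f1 (519.8) the strongest and with Cdk2 and CycA without one. Of 15 insulator and architectural protein genes 9 had a peak (60.0%, 2.38-fold, exact test, adjusted p = 0.015). Chro (6284), Cp190 (2678), pzg (1631) and M1BP (1592) led this list, and Clamp and Ibf1 had none. Both lists are small, and in each the replicates' own lists gave 9 or 10 genes. The cell cycle list did not pass with a window of 200 bp (5 of 18 genes, 1.52-fold, exact test, adjusted p = 0.51), among the 3815 strongest peaks (adjusted p = 0.077) or without replicate 3 (adjusted p = 0.069). The insulator list did not pass with a window of 1000 bp (exact test, adjusted p = 0.064) or without peaks that hold a CTCF-type sequence (8 of 15 genes, adjusted p = 0.052).

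Gene families with few or no peaks at their starts were chemosensory receptors, histones and cytochrome P450 genes. None of 179 genes for odorant, gustatory and ionotropic receptors had an IDR summit (Wilson upper bound 2.10%, exact test, adjusted p = 4e-22), Gr10a and Gr10b among them, and 12 of them had a peak in the relaxed pooled list. None of the 111 replication-dependent histone genes, among them His1:CG31617 and His1:CG33801, had one either (upper bound 3.35%, exact test, adjusted p = 9.9e-14), but none had a relaxed peak, so that this repeated gene cluster could not have passed. Of 83 cytochrome P450 genes, which encode oxidising enzymes, 4 had a peak (4.82%, 0.190-fold, exact test, adjusted p = 6.9e-06), namely Cyp6u1 (1549), Cyp310a1 (1081), Cyp9f2 (474.4) and Cyp317a1 (277.7), while Cyp12a4 and Cyp12a5 had none. With only the 7540 genes that had a relaxed peak as background, the cytoplasmic ribosomal proteins (74 of 82 genes, 1.95-fold, exact test, adjusted p = 2e-15) and the chemosensory receptors (none of 12 genes, adjusted p = 0.0069) passed, and the mitochondrial ribosomal proteins (39 of 64 genes, 1.31-fold, exact test, adjusted p = 0.13), insulator proteins (1.29-fold), cell cycle regulators (1.39-fold) and P450 genes (0.475-fold) did not.

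The remaining lists did not pass the test after adjustment. Of 17 Polycomb group genes, which encode repressors of developmental genes, 8 had a peak (47.1%, exact test, p = 0.049, adjusted p = 0.13), including ph-p (6437), E(z) (1985), Su(z)12 (1021) and Sfmbt (480.3). Trithorax group genes had a peak in 6 of 13 cases (brm 2547, Trl 701.4, skd 356.9, mor 344.4), and germline and piRNA genes in 6 of 13 (piwi 736.3, bgcn 552.8, spn-E 441.2, gcl 414.0). Proteasome subunit genes had one in 15 of 48 cases (Rpn3 970.6, Rpn5 782.4, Rpn11 371.3, Rpn6 343.0), respiratory complex I genes in 11 of 40 (ND-ASHI 1244, ND-MWFE 971.8, ND-51 705.8, ND-24 686.9), heat shock genes in 5 of 16 (Hsp27 3313, Hsp83 1187, Hsp26 895.4, Hsp22 646.2) and DNA replication factors in 5 of 15 (Mcm2 534.8, dpa 475.6, dup 279.4, Mcm5 236.8). Glutathione S-transferase genes had one in 4 of 35 cases (GstE13 2219, GstE12 285.3, GstT4 249.1, GstD1 216.8), and none of 16 Jonah protease genes did (exact test, adjusted p = 0.052). The trithorax group passed when genes sharing a start cluster were counted once, and the Jonah proteases without replicate 2.

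None of the lists of genes that pattern the early embryo passed the test. A peak was found at 2 of 8 homeotic genes (lab 309.6, Antp 233.7), 3 of 12 gap and maternal genes of the anterior-posterior axis (bcd 385.1, cad 270.2, oc 193.1), none of 9 pair-rule genes, 4 of 14 segment polarity genes (nkd 1639, ci 282.8, ptc 226.3, fu 192.5) and 3 of 20 dorsal-ventral genes (pnr 254.8, ush 232.8, rho 199.9). Neurogenesis regulators had one in 6 of 19 cases (elav 3593, grh 901.3, nerfin-1 344.1, pros 265.4), genes of the Enhancer of split complex, targets of Notch signalling, in 4 of 11 (E(spl)m7-HLH 3691, E(spl)m3-HLH 2634, E(spl)mdelta-HLH 1536, E(spl)mbeta-HLH 213.3), and mesoderm and muscle regulators in 6 of 17 (stumps 2775, tin 2107, Tm1 1089, htl 911.2). Adjusted p values of the exact test ran from 0.23 to 1.

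**Figure D3:**
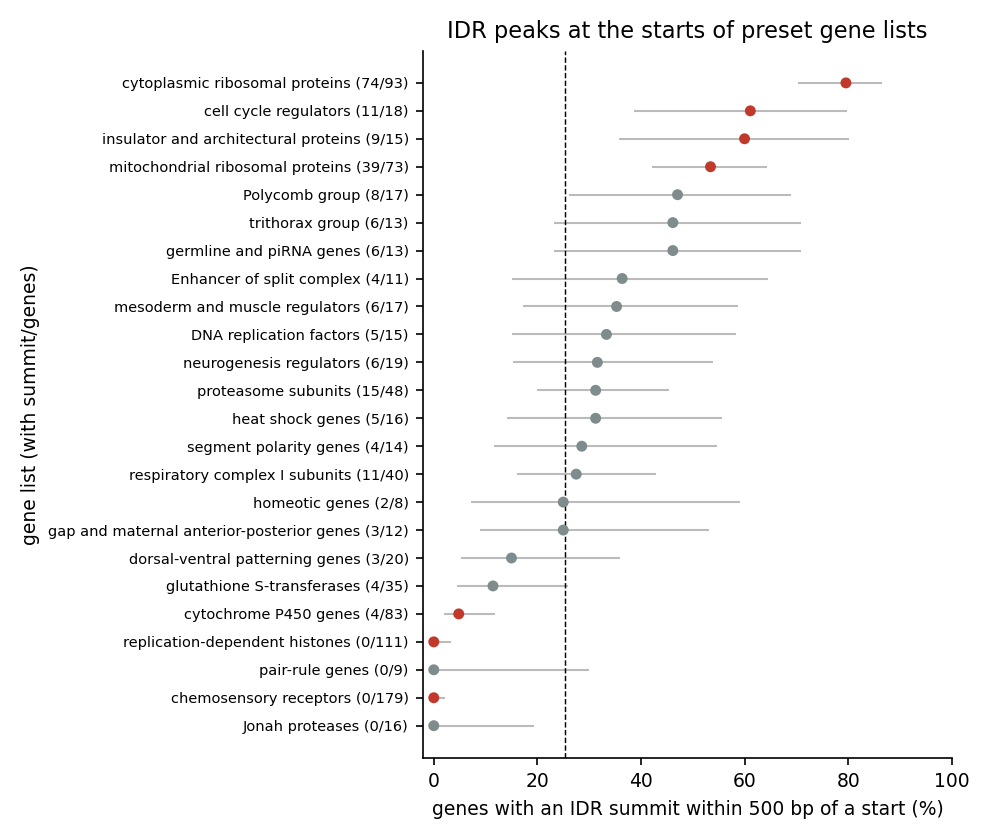
Share of genes in each preset list with an IDR summit within 500 bp of a start (horizontal, %), with 95% Wilson intervals. The dashed line marks the 25.2% of all protein-coding genes, and red dots mark the 7 lists past an adjusted p of 0.05. The cytoplasmic ribosomal proteins stood at 79.6%.

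Sequence at the summits was rich in A and T. In the windows reaching 50 bp to either side of IDR summits the GC content was 31.8% ± 9.51 (SD over peaks), against 44.7% in the flanking windows 300 bp away, a difference of −12.9 points, with −13.6 in replicate 2 and −11.4 in replicate 3. It was −10.6 points at gene starts, −14.4 elsewhere, −16.0 for the 3815 strongest peaks and −1.26 for the other pooled peaks. Of 2080 6-mers counted on both strands, 575 were more frequent at summits than in flanks and 1169 less frequent (exact sign test with Benjamini-Hochberg adjustment), and 524 of the 575 were called in both replicates. All 36 6-mers made only of A and T were among the first group. The 5 with the smallest p were AAATAT (36.9% of summits against 13.9% of flanks), ATATTA (24.0% against 6.32%), TTAAAA (34.6% against 13.3%), AATATA (27.5% against 8.60%) and ATTTAA (31.5% against 11.5%), each higher in both replicates. Against windows of the same GC content outside relaxed peaks, a control chosen after seeing the data, 9.66% of the 6-mers were higher, in place of 27.6%. ATATTA was then 1.21-fold and AAATAT 1.10-fold as frequent, and TTAAAA, AATATA and ATTTAA no longer passed (1.05-fold, 1.04-fold and 1.03-fold). The words with the highest folds there were rich in G and C, among them ACCGCG (3.20-fold), GGCGCC (2.88-fold) and GCGCCA (2.82-fold, 3.70% of summits against 1.31%), which were chosen after their values were seen.

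**Figure D4:**
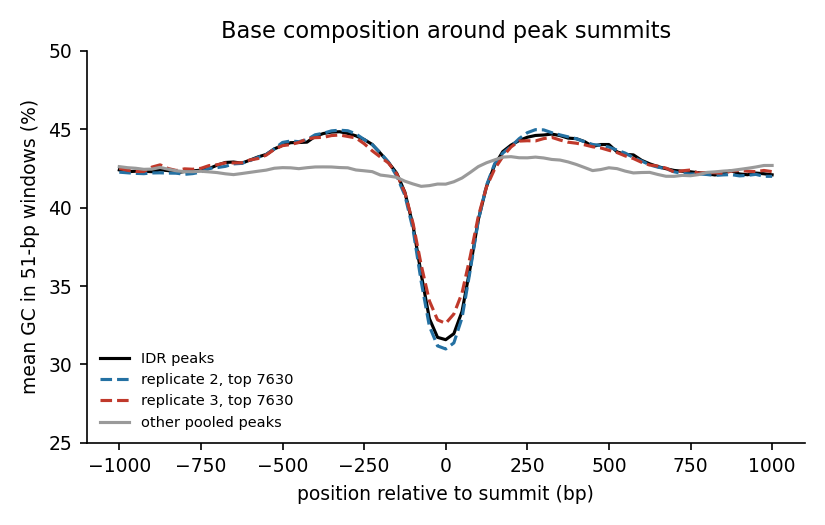
Mean GC content in 51-bp windows (vertical, %) by position relative to the summit (horizontal, bp) for the IDR peaks, each replicate's top 7630 peaks and the 22370 other pooled peaks. The dip at the summit is present in both replicates and nearly absent in the other pooled peaks, whose summits differed from their flanks by −1.26 points.

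Of 33 preset motifs, 11 were more frequent at summits than in flanks and 15 less frequent. The TATA box (26.1% against 9.48%), the homeobox core (11.5% against 5.40%), GATA (10.4% against 5.98%), the Su(Hw) core (8.51% against 5.74%), AGGATA (3.25% against 2.29%) and a run of A (7.52% against 5.94%) were among the higher ones. So were motifs of core promoters and insulators, namely DREF (1.31% against 0.387%), M1BP (0.537% against 0.183%), Ohler motif 6 (1.14% against 0.550%), BEAF-32 (12.9% against 11.0%) and the CTCF core variant AGATGGC (2.06% against 1.11%). Each was called in both replicates except M1BP, which did not pass in replicate 2. Against pooled peaks without an IDR call, matched for position at starts, the TATA box (1.94-fold, Fisher's exact test, adjusted p = 1.3e-85), the homeobox core (1.89-fold), GATA (1.36-fold), the run of A (1.32-fold), the CTCF core variant (1.31-fold, adjusted p = 0.048) and the Su(Hw) core (1.30-fold) were more frequent. In that comparison BEAF-32 (0.859-fold, Fisher's exact test, adjusted p = 3.7e-04) and M1BP (0.586-fold, adjusted p = 0.013) were less frequent, and DREF (0.909-fold), Ohler motif 6 (0.978-fold) and AGGATA (1.06-fold) did not pass. Against windows of the same GC content the TATA box was 1.07-fold as frequent (Fisher's exact test, adjusted p = 0.042), in place of 2.76-fold against flanks. GATA was 1.22-fold as frequent, in place of 1.75-fold, and the Su(Hw) core 1.14-fold, in place of 1.48-fold, both past the exact test (adjusted p = 4.7e-04 and 0.042). DREF (5.26-fold, exact test, adjusted p = 4.8e-13), M1BP (41 summits against 1 window, adjusted p = 2e-10), the CTCF core variant (2.49-fold, adjusted p = 1.2e-09) and BEAF-32 (1.20-fold, adjusted p = 1.7e-04) were more frequent as well. These windows lay more than 500 bp from relaxed summits and were not matched for position at starts. Their folds for core promoter motifs therefore do not tell IDR peaks from gene starts at large. The run of A was less frequent than in these windows (0.682-fold, exact test, adjusted p = 1.3e-12), and the homeobox core (0.949-fold), AGGATA (0.895-fold) and Ohler motif 6 (1.36-fold) did not pass.

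The lower motifs included the runs of G (0.682% against 3.83%) and of CA repeats (0.983% against 3.96%), GAGA factor (0.839% against 2.82%), a partial Dorsal site (24.9% against 29.8%) and Pho (4.60% against 6.95%). So were 3 E-boxes (CACGTG 0.524% against 1.41%, CAGCTG 2.98% against 4.70%, CAGGTG 2.29% against 3.94%), the CTCF core AGGGGGC (0.393% against 1.19%) and the word CAGCCTG (0.236% against 0.872%). CAGCCTG was the only word scored for Ohler motif 7, and its result does not stand for that motif. Grainyhead (0.0393% against 0.210%), a DPE-like motif (0.157% against 0.393%), Zelda (0.393% against 0.623%), its shorter variant (1.66% against 1.93%) and CRE (0.0655% against 0.177%) were lower as well. Grainyhead and the shorter Zelda variant did not pass in replicate 2, nor CRE in replicate 3. Against pooled peaks without an IDR call, matched for position at starts, Grainyhead, CRE and both Zelda motifs did not pass. All other lower motifs stayed less frequent in that comparison, among them GAGA factor (0.352-fold, Fisher's exact test, adjusted p = 1.1e-13), CAGCTG (0.578-fold) and the CTCF core (0.423-fold). Against windows of the same GC content CAGCTG (1.71-fold, exact test, adjusted p = 4.1e-06) and CAGGTG (1.33-fold, adjusted p = 0.042) were more frequent, and GAGA factor (1.36-fold), both Zelda motifs (1.88-fold and 1.15-fold) and the CTCF core (1.20-fold) had values above 1 that did not pass. Runs of G (1-fold, 52 against 52 windows), CA repeats (0.806-fold), CACGTG (0.833-fold) and CAGCCTG (0.692-fold) did not pass there either. Nor did Grainyhead (0.75-fold), the DPE-like motif (0.706-fold) and CRE (0.714-fold), which left only the partial Dorsal site (0.920-fold) and Pho (0.844-fold) less frequent. The other 7 preset motifs, for ZIPIC and Pita, the Initiator, TAGteam, Ets, the heat shock element, AP-1 and Stat92E, did not pass against flanks, although the Initiator did in replicate 3 alone and TAGteam in replicate 2 alone. Against windows of the same GC content the Initiator was more frequent (1.13-fold, exact test, adjusted p = 0.0068). In the comparison with pooled peaks matched for position at starts, the ZIPIC and Pita motif was less frequent (0.598-fold, Fisher's exact test, adjusted p = 0.0088). The others, among them the Initiator (0.959-fold), did not pass in that comparison.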

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

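Windows matched on GC content, 1 start per gene, and lists without peaks that hold a CTCF-type sequence were tests chosen after seeing the data. The replicate overlap (67.2 to 89.7%) and the promoter share (27.9 to 50.6%) kept their direction and passed their tests under every alternative run for them. Single arms, lists, 6-mers and motifs kept direction and call in 235 of 299 comparisons, lost the call in 48 and reversed in 16. Reversed here means a fold on the other side of 1, whether or not it passed its test. The signal correlation was 0.891 with overlap of at least 1 bp and 0.909 in the 3815 strongest IDR peaks. The promoter signal difference was −0.26 with a 200 bp window, −0.050 with a 1000 bp window (permutation p = 0.11), between −0.16 and −0.0088 without replicate 2 or 3, and reversed to 0.20 in the 3815 strongest peaks. In all IDR peaks 5 arms were called, and 3 were without replicate 2, 3 without replicate 3 and 3 in the 3815 strongest peaks, of which only 2R and 3L were called each time. Against chromosome length 3R (0.978-fold) and X (1.07-fold) reversed. With genes that had a relaxed peak as background, 2 of the 7 gene lists were called, and 5 to 8 lists under the other alternatives. Against GC-matched windows 9.66% of 6-mers were higher, in place of 27.6%, and GAGA factor (1.36-fold), Zelda (1.88-fold) and its variant (1.15-fold), the E-boxes CAGCTG (1.71-fold) and CAGGTG (1.33-fold), the CTCF core (1.20-fold), AGGATA (0.895-fold), the homeobox core (0.949-fold) and the run of A (0.682-fold) reversed. Against promoter-matched relaxed peaks DREF (0.909-fold), BEAF-32 (0.859-fold), M1BP (0.586-fold) and Ohler motif 6 (0.978-fold) reversed, as did BEAF-32 in the 3815 strongest peaks (0.961-fold). Of the motifs reversed against GC-matched windows, only CAGCTG, CAGGTG and the run of A passed the exact test there. Against promoter-matched peaks only BEAF-32 and M1BP did. The cause was not tested for any of these. No paired analysis was possible because the series has 1 group. Depth is unknown, so what it limits cannot be stated.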

Other observations

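For the ribosomal protein genes, the tests of promoter GC and of the number of starts were set down before their values were seen. All others below, among them that of promoter composition for the GC dip, and the lists of the next paragraph, were chosen after seeing related values.

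Genes for translation factors and for aminoacyl-tRNA synthetases also carried IDR summits at their starts more often than the remaining protein-coding genes. Of 51 genes for translation initiation and elongation factors 22 did (43.1%, 1.71-fold, Fisher's exact test, adjusted p = 0.010 over 11 lists), with eIF4EHP (signal value 3541), eIF6 (1260) and eEF1gamma (1147) the strongest, and of 32 aminoacyl-tRNA synthetase genes 15 did (46.9%, 1.86-fold, adjusted p = 0.012), led by IleRS (1594) and SerRS (1081). Genes for respiratory complexes III to V (13 of 40), splicing snRNP proteins (4 of 11), the COP9 signalosome (3 of 8) and snRNAs (8 of 32) did not pass. By the same exact test, cuticle protein genes (1 of 95, adjusted p = 1.6e-10), odorant-binding protein genes (2 of 51, adjusted p = 2.8e-04), snoRNA genes (16 of 269, adjusted p = 1.4e-15) and tRNA genes (37 of 290, adjusted p = 8.5e-07) had them less often. Of 3815 genes with a divergent neighbour starting within 500 bp 1830 had a summit (48.0%), against 16.7% of other genes. A single summit there counts for both neighbours. The shares of the translation factor and synthetase genes (43.1% and 46.9%) lay below that 48.0%. The Wilson intervals of the mitochondrial ribosomal proteins (42.1 to 64.4%), the insulator proteins (35.7 to 80.2%) and the cell cycle regulators (38.6 to 79.7%) held 48.0%. The interval of the cytoplasmic ribosomal proteins (70.3 to 86.5%) lay above it. None of the 11 lists was tested against only genes with a relaxed peak. Genes that could not have passed, as at the histone cluster, were therefore not set apart, also among tRNA and snoRNA genes.

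Peaks with a sequence like the core of the CTCF binding site stood apart between the replicates. The 213 matched IDR peaks with AGGTGGCG, AGATGGCG, AGAGGGCG or AGGGGGCG had a median log2 replicate 2 to replicate 3 ratio of −0.40, against 0.29 for the other 7138, but these words were picked after the ratios were seen, so that this difference describes the pattern and does not test it. Of the 100 strongest matched peaks with a ratio below 0, 49 held such a word, against 0 of the 100 strongest with a ratio of 0 or more. Median summit GC of these sets was 42.6% and 25.7%. The 153 peaks with AGATGGC, a variant fixed beforehand for the comparison with flanks, had a median of −0.16, lower than peaks without it by a difference of −0.44 (permutation p = 1e-05, the smallest that 100000 resamples can give). AGATGGC lies within the picked word AGATGGCG, held by 102 matched peaks, and its ratio was examined after the pattern was seen. It is therefore not an independent test. By word, the median was −0.56 in 82 peaks with AGGTGGCG and −0.03 in 15 with AGGGGGCG, which contains the preset CTCF core. With other peaks weighted to the same summit GC the difference was −0.30 for AGATGGC (95% bootstrap interval −0.45 to −0.14) and −0.45 for the picked words (−0.58 to −0.34). Weighted to the same promoter status and signal it was −0.45 (−0.64 to −0.31) and −0.70 (−0.81 to −0.59). The words were picked after the ratios were seen, and AGATGGC shares peaks with them. The differences that remained after weighting therefore do not decide whether base composition or location is the whole cause. Reads of another immunoprecipitation mixed into replicate 3, or a real difference between the embryo collections, may each give such bands, and neither was tested, since no CTCF library was used here and the series has 1 group.

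The dip of GC at IDR summits was weighed against 3 explanations. Of the 7630 windows with the lowest GC that were not mostly repeat-masked, 11.1% lay within 100 bp of a relaxed pooled summit, against 4.71% of all such windows. The IDR summits that show the dip are among these summits, so that the comparison does not decide whether a bias toward AT-rich sequence is part of the cause, and this stays open. The dip was −14.4 points away from gene starts and −10.6 at starts, so that promoter composition is not the whole cause. No 6-mer of A and T alone that passed the test exceeded 1.21-fold over GC-matched windows, so that none stood out by much beyond base composition. Such words are common in these windows (ATATTA in 19.8%), which limits the fold. The comparison therefore does not decide whether 1 such word is part of the cause. Preference of the tagged protein for AT-rich DNA may also remain, as a hypothesis, and beyond the comparison of single 6-mers no biological explanation was tested.

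The high share of cytoplasmic ribosomal protein genes with a summit (79.6%, Wilson interval 70.3 to 86.5%) was weighed in the same way. Other genes weighted to the same lowest GC around their starts had a share of 25.7%, and weighted to the same number of starts 29.1%, both below that interval. Without the 22 copies named after another member, proteasome and complex I genes had 39.4% (26 of 66). Fisher's exact test against the ribosomal protein genes gave p = 3.6e-07. None of the copies had a summit, and with them the share was 29.5%. The shares of the proteasome and complex I lists had been seen before this comparison was chosen. It therefore describes a lower share in these complexes and does not test the explanation. Whether a share common to housekeeping genes at large is part of the cause stays open. Very high transcription of ribosomal protein genes, which may raise background in an immunoprecipitation, was not tested and stays open. No biological explanation was tested.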
